A study of Glycine max with 42 samples.

How the data were processed

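RNA was taken from trifoliate leaves of soybean (Glycine max) and sequenced as 42 libraries, 3 in each of 14 groups. Williams 82, a soybean cultivar, supplied 27 libraries: an initial group at day 38 after planting, and depodded and control groups at days 45, 54, 64 and 76. Line T295H supplied 15 libraries: an initial group at day 28, and sterile and control groups at days 35 and 63. Depodding is the removal of pods, which takes away the seeds as a sink for what the leaf exports, and in the sterile plants the sink was limited genetically.

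The values deposited by the authors are a signal per gene and library, in 1 table per line. From the values, each column holds whole multiples of a single step, as gene counts divided by 1 size factor per library would give. The submitters' processing notes name Bowtie2 and DESeq2, with no version or role. The genome build, the annotation, the counting tool and whether strand was used are not given in the sources used here. Dividing by the step gave whole counts within 0.01 for 100% of values, with a largest deviation of 8.5e-05 in the Williams 82 table and 7.2e-05 in the T295H table. Recovered totals ran from 6663477 to 13166094 counts per library in Williams 82 and from 5471456 to 11877733 in T295H.

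Of the recovered counts above 0, 98.9% in Williams 82 and 99% in T295H were even, and the share lay between 98.8% and 99.2% in every library. Why the counts are even is not stated in the sources used here. A count was therefore not treated as an independent observation, and floors and counting intervals were computed on pairs of counts. A fold against a group with no count was computed against a floor of 3 pairs per library (6 counts), equal to a normalised count of 3.8 to 11.9 in the Williams 82 libraries and 4.22 to 19.3 in the T295H libraries. Floors and 95% intervals (exact Clopper-Pearson) cover counting error only.

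The tables list 38177 genes for Williams 82 and 37403 for T295H, and 36023 IDs are in both. All IDs of the T295H table carry a numbered ending that those of the Williams 82 table lack, and it was removed to match them; what it stands for is not given in the sources used here. The tables were normalised separately, so every test stayed within a table. No 2 libraries of a group were within sampling noise of each other: the lowest chi-square per degree of freedom, on pairs of counts, was 3.33.

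The main test was limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) in R 4.3.3, on log2(normalised count + 1), two-sided, with Benjamini-Hochberg adjustment within each comparison and an adjusted p under 0.05 as the threshold. Genes with a mean of at least 10 over the libraries of their table were tested, 29208 in Williams 82 and 29370 in T295H, of which 27751 were tested in both. All groups of a table entered 1 fit with 1 mean per group and shared an estimate of the spread. Fold changes on the log2(value + 1) scale understate the change of low genes. The labels do not say that the 3 libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

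The day of a library was taken from its time point label. For the depodded groups this conflicts with the sampling number in the library titles: the depodded libraries labelled day 64 carry the number 5, which the controls carry at day 76, and those labelled day 76 carry the number 4, which the controls carry at day 64. The label was kept for the main grouping and the title number was an alternative. The groups are called the depodded libraries labelled day 64 and labelled day 76.

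The files do not pair gene IDs with names, and 0 of 39557 IDs matched any of the 59048 genes of the RefSeq table used as reference (assembly Glycine_max_v4.0). The 33 gene lists fixed by product name, markers of seed, nodule, root, flower and pollen among them, could therefore not be applied to any comparison, and no check of GC content or gene length was possible. Group means of named genes of at least 20 that a single library moved by more than 1.5 times are given with the mean without it. Named genes follow the rule set for that case: per comparison, the 2 higher and 2 lower genes with the largest absolute log2 change among those past the threshold, with a mean of at least 50 in the higher group and no overlap between the libraries of the groups. For the overlap of depodding and sterility, the 2 genes per direction with the largest smaller change of both were taken. Genes that share reads with near-identical copies, overlap another gene or lie antisense to it could not be recognised, so every named gene is uncertain in that respect.

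The initial groups carry no label of control, sterile or depodded, so a change over time here is that between initial leaves and controls of the last day. As groups of genes, those that rose and those that fell between these groups of a line were followed in the other line, with which they share no library. Their shift was tested with camera (limma), which compares a list with all other genes, with a preset correlation of 0.01 between genes and again with an estimated correlation, and p-values were adjusted over the 12 tests of that family. Alternatives were a pseudocount of 5, no filter, a mean of at least 50, TMM rescaling, a fit of only the compared groups, the replicate number as a block, each library left out in turn, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered counts, and the title numbers. These choices, other than camera on the time lists, were made before the data were examined. Added after seeing the data were the camera tests, the Williams 82 time lists, the T295H lists at other days than 76, a fit without the initial libraries, edgeR and DESeq2 on halved counts, the similarity to the initial libraries, the overlaps at day 54, at the label of day 64 and of the time courses, and the tests of the difference between days 63 and 35 and between days 76 and 64.

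The limma fit was tested on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold. For the comparison of day 54, with 29208 genes, it recovered 62 of the former and 97 of the latter and called 6 unchanged genes. For sterile against control leaves at day 35, with 29370 genes, it recovered 93 and 99 and called 6 unchanged genes. Each is a single simulated draw, and the numbers vary with the draw. Every gene was given the same spread in all groups, and changed genes were not drawn from those with the lowest control means. The simulation therefore cannot show how the shared fit behaves where groups differ in spread or where genes are low.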

Results

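Gene expression was measured by RNA sequencing in soybean leaves, in a time course that began at R2, a flowering stage, and ended when leaves began to senesce. The seed sink was limited by depodding in Williams 82 and by sterility in T295H, and each line had its own controls and an initial group, whose labels do not say which kind of plant it came from. Each of the 14 groups held 3 libraries, with 6663477 to 13166094 counts per library in Williams 82 and 5471456 to 11877733 in T295H. Values are normalised counts, as mean ± SD over n = 3 libraries, and adjusted p-values are from limma. For each named gene, every library of the higher group was above every library of the lower group.

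The first question was how leaves changed with age, from the initial group to the last controls. In Williams 82, 5882 genes were higher and 6908 lower in controls of day 76 than in initial leaves of day 38, out of 29208 tested. Glyma.11G093100 rose from 2.73 ± 2.61 to 13600 ± 1930 (log2 change 12.18, SE 0.8, adjusted p 2e-10), and Glyma.06G307900 from 1.73 ± 3 to 5790 ± 1780 (log2 change 11.57, SE 0.91, adjusted p 2.1e-09). Glyma.15G238600 fell from 49900 ± 14300 to 2.82 ± 3.05 (log2 change -14.03, SE 0.79, adjusted p 2.1e-11) and Glyma.04G065600 from 43900 ± 24500 to 8.67 ± 2.79 (log2 change -12.05, SE 0.81, adjusted p 2.8e-10). The initial libraries held 6 counts of Glyma.11G093100 and 4 of Glyma.06G307900 in all, so the ratios of 5000 (95% counting interval 1510 to 21400) and 3340 (773 to 23100) are imprecise. The former was 3330 without initial replicate 1 and 9140 without initial replicate 2, and without initial replicate 2 the latter was at least 556. A fit of only these 6 libraries called 7839 genes.

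In T295H, 9204 genes were higher and 9429 lower in controls of day 63 than in initial leaves of day 28, out of 29370 tested. Glyma.05G126800 rose from 8.6 ± 7.44 to 26500 ± 4740 (log2 change 12.15, SE 0.86, adjusted p 1.2e-08), and Glyma.07G056800 from 1.43 ± 2.48 to 7130 ± 600 (log2 change 11.99, SE 0.65, adjusted p 6.3e-10). Both initial means lay under the floor of these libraries, 11.1. The initial libraries held 4 counts of Glyma.07G056800 in all, so its ratio of 4970 (95% counting interval 1010 to 30200) is imprecise. It was at least 533 without initial replicate 3. Glyma.16G165200 fell from 63000 ± 24700 to 12.4 ± 5.65 (log2 change -12.21, SE 0.47, adjusted p 2.3e-11) and Glyma.13G250400 from 9400 ± 3070 to 4.65 ± 6.58 (log2 change -11.41, SE 1.25, adjusted p 1.3e-06). In T295H initial replicate 2, the 10 most abundant genes held 41.3% of counts (95% Clopper-Pearson interval 41.3 to 41.4), and without this library 17887 genes were called. Among genes with a mean of at least 50, 6883 were higher and 6698 lower, the opposite balance. Among the 27751 genes tested in both lines, 3773 rose in both time courses (1829 for independent lists) and 4930 fell in both (2040), while 642 went opposite ways. In fits of only the compared groups, the 8703 genes that changed the same way became 5721. The changes of the lines correlated across genes with Pearson's r 0.787 and Spearman's rho 0.664, and genes are not independent replicates.

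Depodded leaves were then compared with controls of the same day, to see when the removal of the mechanical sink changed expression. At day 45, 3 of 29208 genes passed the threshold, 1 higher and 2 lower, while 3046 had an unadjusted p under 0.05 against 1460 by chance. The higher gene, Glyma.02G156800, stood at 121000 ± 161000 in depodded and 1900 ± 675 in control leaves (log2 change 5.07, SE 0.79, adjusted p 0.029). Depodded replicate 3 carried this mean, which was 28500 without it. Its call was lost in the fit of only the compared groups, with the replicate number as a block, with edgeR on recovered and on halved counts, and without depodded replicate 2 or any 1 of control replicates 1, 2 and 3. EdgeR called 0 genes on recovered counts (3075 at an unadjusted p under 0.05) and 0 on halved counts (3217), DESeq2 called 130 (71 higher and 59 lower) and 107 (54 and 53), and limma called 0 in the fit of only the compared groups, 0 with the block, 1 higher gene with a pseudocount of 5, and 1 higher and 1 lower among genes with a mean of at least 50. Without depodded replicate 1, 2 or 3, 9, 0 and 19 genes were called, and without control replicate 1, 2 or 3, 1, 0 and 0, against 3046 genes at an unadjusted p under 0.05 with all libraries.

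At day 54, 156 genes were higher and 101 lower in depodded leaves. Glyma.02G156800 reached 173000 ± 71600 against 397 ± 408 in controls (log2 change 9.18, SE 0.79, adjusted p 1.4e-06), and Glyma.17G212200 stood at 438 ± 382 against 0.53 ± 0.918 (log2 change 7.89, SE 1.52, adjusted p 0.019). The control libraries held 2 counts of the latter, which gives a ratio of 827 with a 95% counting interval of 166 to 36800. Without control replicate 1, the control mean of Glyma.02G156800 was 163, and without depodded replicate 1 the depodded mean of Glyma.17G212200 was 227 and the ratio 428. Without control replicate 2 that ratio was at least 93.4. Glyma.01G178800 was lower, at 8.04 ± 8.95 against 317 ± 247 (log2 change -5.65, SE 1.3, adjusted p 0.038; 178 in controls without replicate 2), and so was Glyma.16G085600, at 24.1 ± 9.95 against 1020 ± 457 (log2 change -5.31, SE 1.21, adjusted p 0.036). DESeq2 called 1375 genes, 671 higher and 704 lower, so that the balance turned, and 1294 on halved counts (649 and 645). The fit of only the compared groups called 2096, a fit without the initial libraries 696 and a pseudocount of 5 gave 393, while leaving out depodded replicate 1, 2 or 3 gave 24, 23 and 155 and control replicate 1, 2 or 3 gave 26, 84 and 138. Glyma.17G212200 and Glyma.01G178800 lost their calls with edgeR on recovered and on halved counts and without any 1 of depodded replicates 1 and 2 and control replicate 1, Glyma.01G178800 also with the replicate number as a block and without control replicate 2 or 3, and Glyma.16G085600 without any 1 of the 6 libraries.

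In the depodded libraries labelled day 64, 5572 genes were higher and 4873 lower than in controls of day 64. Glyma.02G156800 stood at 151000 ± 80600 against 113 ± 62.3 (log2 change 10.35, SE 0.79, adjusted p 1.1e-08) and Glyma.06G084200 at 9360 ± 5700 against 8.01 ± 8.59 (log2 change 10.18, SE 0.76, adjusted p 8.5e-09). Glyma.03G032400 was at 0.544 ± 0.943 against 1110 ± 717 in controls (log2 change -9.37, SE 1.68, adjusted p 0.00019), a ratio of 2030 with a 95% counting interval of 361 to 79500, and at least 200 without depodded replicate 3. Glyma.20G129000 had no count in these depodded libraries and was at least 135-fold lower than in controls, at 721 ± 765 (adjusted p 0.00029), or at least 54.2-fold lower without control replicate 3, with controls at 289. With the days taken from the title numbers, 2067 genes were higher and 1733 lower, and Glyma.03G032400, at 162 ± 143 in depodded leaves (104 without depodded replicate 2), lost its call (log2 change -4.1, SE 1.68, adjusted p 0.11). Glyma.20G129000 then stood at 28.4 ± 33.2 in depodded leaves, a ratio of 25.4 to controls (log2 change -5.35, SE 1.66, adjusted p 0.036). Its depodded mean was 10.1 without depodded replicate 2 and its control mean 289 without control replicate 3, so this ratio depends on single libraries. Glyma.06G084200 then stood at 1430 ± 608 (log2 change 7.67, SE 0.76).

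In the depodded libraries labelled day 76, 7060 genes were higher and 6477 lower than in controls of day 76. Glyma.07G115500 stood at 10800 ± 7060 against 1.65 ± 1.61 (log2 change 12.02, SE 0.82, adjusted p 1.2e-09), a ratio of 6530 with a 95% counting interval of 2330 to 33000, and at 6740 without depodded replicate 1. That ratio was 4090 without this replicate, and 12400 and 4350 without control replicate 2 or 3. Glyma.02G156800 stood at 136000 ± 28100 against 46.4 ± 28.4 (log2 change 11.63, SE 0.79, adjusted p 1.2e-09), with 30 in controls without replicate 3. Glyma.05G126800 and Glyma.07G056800, the genes named above as risen in T295H, were lower here: the former at 1.23 ± 2.12 against 11000 ± 13000 (adjusted p 1.2e-07), a ratio of 8930 with a 95% counting interval of 2420 to 72200, and of at least 1880 without depodded replicate 3, and the latter with no count against 2570 ± 1870 (adjusted p 9.9e-07), at least 449-fold lower. Control replicate 3 carried both control means, which were 3450 and 1620 without it, with a ratio of 2820 for the former gene and at least 283-fold lower values for the latter. Among genes with a mean of at least 50, the balance turned, with 5069 higher and 5119 lower. By the title numbers, 4601 genes were higher and 3664 lower, and Glyma.05G126800 stood at 291 ± 127 in depodded leaves, 37.6-fold lower than in controls (log2 change -4.58, SE 1.21, adjusted p 0.0062). Glyma.07G056800 had no count there either and was at least 482-fold lower. The folds of Glyma.05G126800 and Glyma.07G056800 by the title numbers also rest on the control means that control replicate 3 carried (3450 and 1620 without it). Glyma.07G115500 then stood at 14700 ± 1100 in depodded leaves. A test of whether the effect differed between days 76 and 45 called 4979 genes with a more positive and 4368 with a more negative effect at day 76, and 5070 genes in all by the title numbers. DESeq2 on halved counts turned that balance, with 5060 more positive and 5120 more negative.

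**Figure D1:**
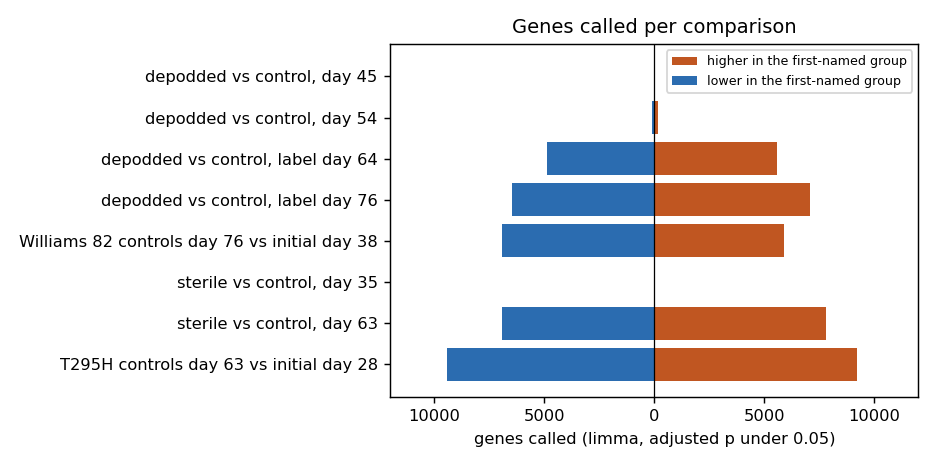
Number of genes called by limma (horizontal axis) in each comparison (vertical axis), to the right those higher and to the left those lower in the group named first. The depodded groups follow their time point labels, and calls range from 3 genes at day 45 to 18633 between T295H controls of day 63 and initial leaves of day 28.

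Sterile leaves were compared with controls within T295H, for the effect of the genetic limitation. At day 35, 28 genes were higher and 24 lower, out of 29370. Glyma.19G024200 stood at 1330 ± 1060 in sterile and 20.6 ± 3.67 in control leaves (log2 change 5.62, SE 0.68, adjusted p 0.004; 740 without sterile replicate 3), and Glyma.15G089000 at 59.4 ± 30 against 1.67 ± 1.52 (log2 change 4.6, SE 0.65, adjusted p 0.01). Glyma.10G205800 was lower, at 6.68 ± 5.42 against 70 ± 5.5 (log2 change -3.48, SE 0.5, adjusted p 0.011), as was Glyma.10G194200, at 6.72 ± 0.9 against 78.7 ± 28.4 (log2 change -3.32, SE 0.46, adjusted p 0.01). DESeq2 called 826 genes (613 on halved counts), edgeR on halved counts 101, the fit of only the compared groups 1119, a fit without the initial libraries 804 (358 higher and 446 lower), a fit with the replicate number as a block 708 (330 and 378) and a pseudocount of 5 gave 95, while leaving out sterile replicate 1, 2 or 3 gave 11, 23 and 10 and control replicate 1, 2 or 3 gave 33, 5 and 5. More genes were lower than higher also without sterile replicate 2 (10 higher and 13 lower) or 3 (3 and 7), and among genes with a mean of at least 50 (21 and 22). Glyma.15G089000 and Glyma.10G205800 lost their calls without sterile replicate 3 or control replicate 2, and Glyma.10G205800 and Glyma.10G194200 without control replicate 3.

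At day 63, 7821 genes were higher and 6946 lower in sterile leaves. Glyma.12G217400 stood at 50000 ± 5140 against 21.4 ± 5.34 in controls (log2 change 11.15, SE 0.52, adjusted p 5.1e-10) and Glyma.14G085600 at 18100 ± 3490 against 8.53 ± 1.57 (log2 change 10.88, SE 0.38, adjusted p 8.1e-11). Glyma.11G144900 was at 3.03 ± 1.29 against 28000 ± 30200 (log2 change -12.24, SE 0.67, adjusted p 2.5e-09), with 10700 in controls without replicate 2, and Glyma.04G039900 had no count against 2170 ± 346 (adjusted p 4.2e-09), at least 464-fold lower. The effect of sterility differed between days 63 and 35 for 7945 genes, 4430 of them with a more positive effect at day 63.

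The comparison of both kinds of sink limitation used the depodded libraries labelled day 76 and the sterile libraries of day 63, which share no library. Of 27751 genes tested in both, 4125 were higher in both (1813 for independent lists) and 3404 lower in both (1494), and 509 were called in opposite directions. Glyma.14G085600 stood at 37300 ± 11400 in these depodded and 18100 ± 3490 in sterile leaves, against 25.9 ± 34.6 and 8.53 ± 1.57 in their controls. Glyma.12G217400 followed at 38900 ± 5800 and 50000 ± 5140 against 98.9 ± 154 and 21.4 ± 5.34. In the initial leaves of Williams 82 the former stood at 17800 ± 7370 and the latter at 10100 ± 8840. Without replicate 2, the Williams 82 control means were 5.99 for the former and 10.2 for the latter, and the initial mean of the latter was 5260. Glyma.07G056800 and Glyma.05G126800 were the lower genes, with log2 changes of -10.98 (SE 1.32) and -11.94 (SE 1.21) in depodded and -10.16 (SE 0.65) and -9.2 (SE 0.86) in sterile leaves. The effects correlated across genes with Pearson's r 0.729 and Spearman's rho 0.645. By the title numbers, 3526 genes were higher and 2671 lower in both and 67 were opposite. The log2 changes in depodded leaves were then -10.98 (SE 1.32) for Glyma.07G056800, -4.58 (SE 1.21) for Glyma.05G126800, 11.37 (SE 0.79) for Glyma.14G085600 and 10.38 (SE 0.99) for Glyma.12G217400. With the depodded libraries labelled day 64 instead, 2309 genes were higher in both (1426 for independent lists) and 2080 lower in both (1133). There, 1228 genes were opposite, with Pearson's r 0.469 and Spearman's rho 0.379. No alternative was run for that overlap, the title numbers included. The tables were normalised separately, so levels are not compared across the lines.

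**Figure D2:**
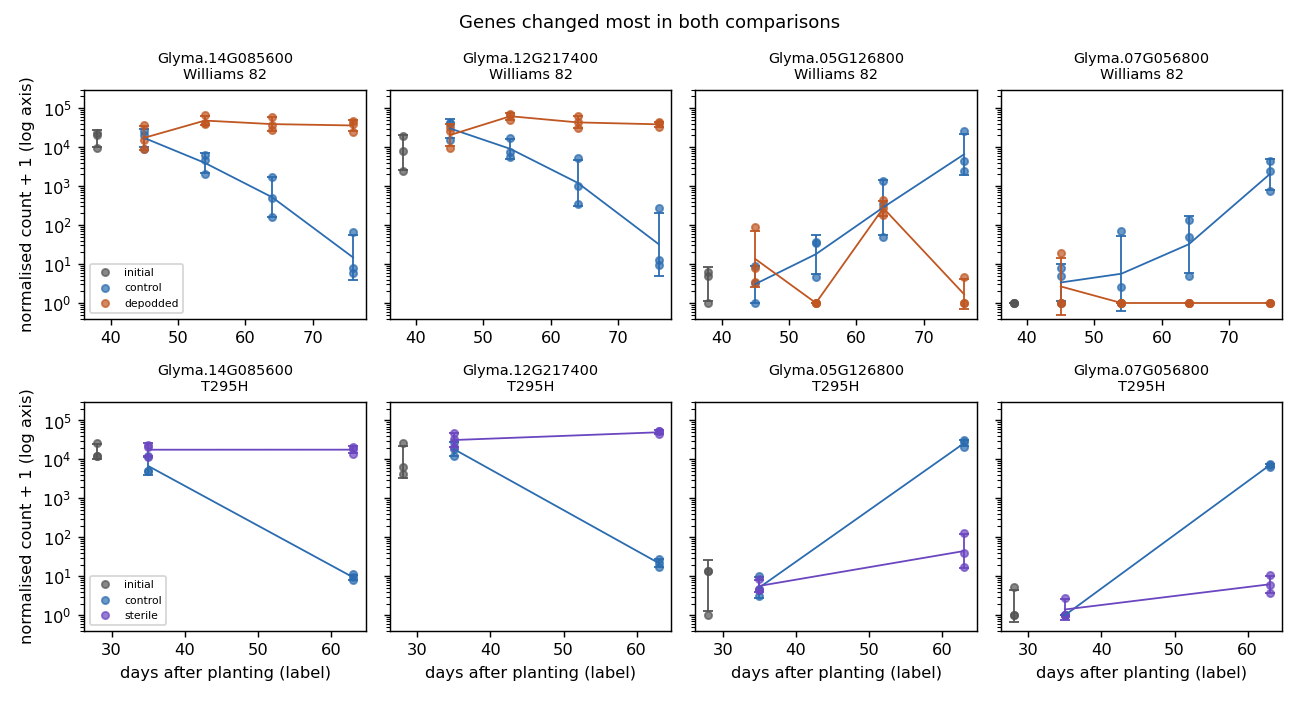
Normalised count + 1 (log axis) of 4 genes against days after planting by label, in Williams 82 and T295H, with a point per library, lines through the means of the log values and bars of 1 SD on that scale. Glyma.14G085600 and Glyma.12G217400 stood between 14200 and 70400 in depodded libraries from day 54 on and in sterile libraries of day 63. In controls, both genes were lower on the last day than in initial leaves. The control mean of Glyma.12G217400 first stood above its initial mean, at day 45 in Williams 82 and day 35 in T295H.

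**Figure D3:**
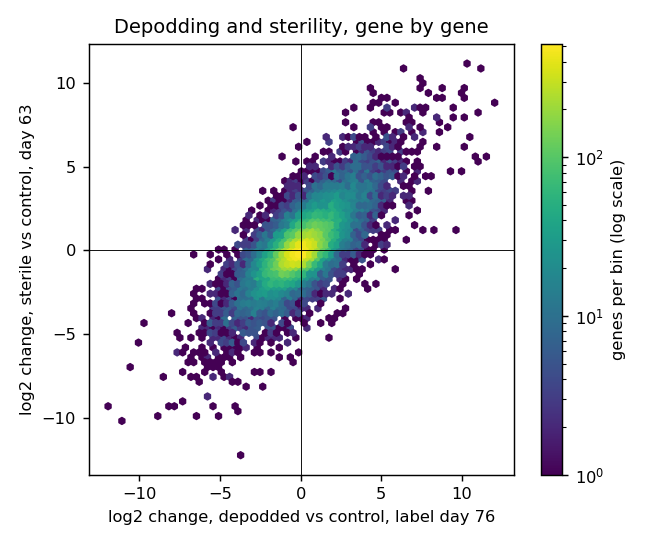
Log2 change between depodded libraries labelled day 76 and controls (horizontal) against that between sterile and control libraries of day 63 (vertical), for 27751 genes, coloured by the number of genes per bin on a log scale. Pearson's r across genes was 0.729.

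Genes that differed between the last controls and the initial leaves of a line were followed in the sink-limited leaves of the other line, to see whether age-related genes differed there. The lists of both lines hold only genes tested in both lines, so they are shorter than the counts given above. Of 8796 genes higher in T295H controls of day 63 than in initial leaves (the risen genes), 4040 were lower and 396 higher in the depodded libraries labelled day 76 (median log2 change -0.78), and of 8820 that were lower (the fallen genes), 4607 were higher and 408 lower (median 0.99). Adjusted over the list alone, 4093 of the former were lower and 4726 of the latter higher. At day 54, 86 of the risen genes were lower and 4 higher, and 134 of the fallen genes were higher and 1 lower. There, adjusted over the list alone, 138 of the risen genes were lower and 6 higher, and 273 of the fallen genes were higher and 2 lower. Those 220 calls of 86 and 134 genes were 23, 23 and 128 without depodded replicate 1, 2 or 3 of day 54 and 26, 72 and 118 without control replicate 1, 2 or 3. They were 341 with a pseudocount of 5, 1769 in the fit of only the compared groups, and 1155 with DESeq2 (1092 on halved counts). Camera called these 4 shifts with the preset correlation, and they held with an estimated correlation (adjusted p = 0.003 for both lists at the label of day 76, and 0.003 and 0.0033 at day 54). At day 45, camera called neither list (adjusted p = 0.51 and 0.33 with the preset correlation).

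In the depodded libraries labelled day 64, 2322 of the risen T295H genes were lower and 833 higher, and 2524 of the fallen genes were higher and 1016 lower, but camera's calls were lost with an estimated correlation (adjusted p = 0.099 and 0.18). Camera was run by the time labels only, not with the title numbers. The order of its results over the labels of days 64 and 76 therefore rests on labels in doubt. Of 5771 genes higher in Williams 82 controls of day 76 than in initial leaves, 2571 were lower and 618 higher in sterile leaves at day 63 (median log2 change -0.59), and of 6420 that were lower, 3725 were higher and 372 lower (median 1.18). With an estimated correlation, camera's call on the fallen genes held (adjusted p = 0.0062) and that on the risen genes was lost (adjusted p = 0.052). At day 35, 13 of the risen genes were lower and 0 higher, and 20 of the fallen genes were higher and 3 lower. Adjusted over the list alone, 15 of the risen genes were lower and 0 higher, and 74 of the fallen genes were higher and 6 lower. Camera's calls on both lists were lost with an estimated correlation (adjusted p = 0.11 and 0.06).

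Resemblance to the initial leaves was followed as the mean correlation of a library with the initial libraries, across genes. It was 0.858 ± 0.0084 in Williams 82 controls at day 45 and 0.614 ± 0.042 at day 76, against 0.838 ± 0.045 in depodded libraries at day 45 and 0.743 ± 0.021 in those labelled day 76. In T295H it was 0.442 ± 0.016 in controls and 0.752 ± 0.011 in sterile leaves at day 63. At days 76 and 63, every sink-limited library was above every control. A two-sided exact permutation test of 3 against 3 libraries cannot go below p = 0.1.

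**Figure D4:**
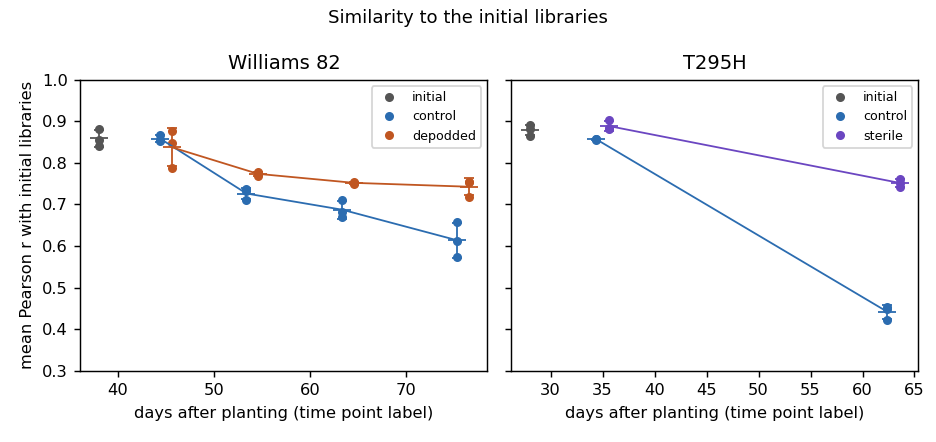
Mean Pearson correlation of each library with the initial libraries of its line (vertical axis, from 0.3) against days after planting by label, with a point per library, the group mean and bars of 1 SD over 3 libraries. Control values fell to 0.614 in Williams 82 and 0.442 in T295H, and those of depodded and sterile leaves to 0.743 and 0.752.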

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

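Of the tests given here, that of neighbouring genes was fixed before its result was seen; the tests of the label exchange, of T295H initial replicate 2, of other splits of the libraries, and of the differences between days 63 and 35 and between days 76 and 64 were chosen after.

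The effect of depodding differed between the labels of days 76 and 45 for 9347 genes and between those of days 76 and 64 for 12578 genes, each by a test of the difference itself. By the title numbers these counts were 5070 and 1385. The effect of sterility differed between days 63 and 35 for 7945 genes. Splits of the 12 libraries cannot test these differences, since splits that keep the real groups of 1 day and regroup the other can call many genes from that day alone. As many genes as in the real split were called in 2, 1 and 10 of 100 splits, the real one included, and the highest others called 9587, 8101 and 12331. Splits that kept the groups of neither day called at most 1, 3 and 0 genes.

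At the labels of days 64 and 76, 3679 genes were called in opposite directions by depodding and 2165 in the same direction. For independent lists, 1236 and 1178 opposite calls and 1347 and 1081 shared ones are due, against 1936 and 1743 opposite ones, 1325 higher in both and 840 lower in both. Across genes the effects were close to unrelated (Pearson's r 0.151, Spearman's rho -0.039). An exchange of the time labels of these depodded groups is a candidate explanation, since the change from label 64 to label 76 in depodded libraries correlated across genes with that in controls at r = -0.49, with -0.45 to -0.23 over 81 choices of single libraries, and the depodded libraries labelled day 76 were closer to those of day 54 (mean r 0.929 ± 0.0035) than those labelled day 64 (0.821 ± 0.013), while controls of day 64 were closer (0.917 ± 0.0062) than those of day 76 (0.78 ± 0.04). The 81 correlations compare single libraries rather than group means and reuse the same libraries, so their range is not an interval for r. With the days taken from the title numbers, 47 genes were called in opposite directions and 1989 in the same direction. A change of direction in the depodded plants themselves cannot be told apart from an exchange by the 3679 opposite calls, because nothing in the values names a day. No library was reassigned.

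Genes called with a change of at least 4 on the log2 scale followed each other on a chromosome more often than random placements gave. Of such genes, 616 were higher and 348 lower in the depodded libraries labelled day 76, and 672 and 475 in sterile leaves at day 63. In the depodded libraries labelled day 76, 65 pairs of neighbouring tested genes changed in the same direction, against a mean of 17 and a highest of 36 in 10000 random placements of as many genes (permutation p = 1e-04, the smallest these placements can give). In sterile leaves at day 63 there were 81, against a mean of 22.8 and a highest of 42 (permutation p = 1e-04, again the smallest). Neighbouring loci may thus change together more often than chance. Whether reads shared between near-identical neighbours add to this was not tested, and it stays open, as does a shared response of neighbouring copies.

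In T295H initial replicate 2, the 10 most abundant genes held 41.3% of counts (95% Clopper-Pearson interval 41.3 to 41.4), against 9.55% (9.53 to 9.58) and 9.2% (9.18 to 9.23) for the most abundant 10 in the other initial libraries, and 6 of the 10 lie on chromosome 13. The count of the T295H time course was 18633 with this library and 17887 without it, so that count does not depend on this library. Leaving the library out does not test the 10 genes alone, which are too few to make up the count. What set the library apart stays open: a few genes taking a large share of the counts is what was measured, and no biological explanation was tested.

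Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. At day 45, 2 of 10 splits called at least the real 3 genes, and the highest other called 6. In the others, only the real split, 1 of 10, called as many. The real values and the highest other splits were 257 and 1 at day 54, 10445 and 1 at the label of day 64, 13537 and 0 at that of day 76, 52 and 0 for sterile leaves at day 35, 14767 and 0 at day 63, 12790 and 45 for Williams 82 controls of day 76 against initial leaves, and 18633 and 1 for T295H controls of day 63 against initial leaves.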

How the results depend on the processing

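The fit without the initial libraries, the tests on halved counts, the differences between days 63 and 35 and between days 76 and 64, the opposite calls at days 64 and 76, the overlaps at day 54 and of the time courses, and the Williams 82 time genes in sterile leaves were chosen after the data were seen. No log2 change of a named gene changed sign under the alternatives run. These genes were chosen for large changes without overlap between the same libraries, so a kept sign was likely from the start. Under the settings given with each, the balance of higher and lower calls turned at days 45, 54, 76 and 35. It also turned so in T295H controls against initial leaves and for the difference between days 76 and 45. The balance of shared and opposite calls at days 64 and 76 turned too. By label, 3679 were opposite and 2165 shared, and by the title numbers 47 and 1989. The counts at the labels of days 64 and 76, in sterile leaves at day 63, in T295H controls against initial leaves, in the overlap of the label of day 76 with sterile leaves, in the T295H time genes at that label, in the Williams 82 time genes in sterile leaves and in the opposite calls stayed within 1.5 times under all alternatives but the title numbers, also with each library left out. In the fit of only the compared groups, 7839 genes were called in Williams 82 controls against initial leaves and 5721 changed the same way in both time courses (8703 with all groups); both stayed within 1.5 times under the other alternatives and with each library left out. The cause was not tested for the values below. Fewer libraries enter the fits of compared groups, those without initial libraries and those that leave a library out. The main fit shares its spread over all groups. The mean correlation within a group was 0.859 and 0.879 in initial libraries of Williams 82 and T295H, and 0.87 in depodded libraries of day 45. It was 0.951 and 0.936 in depodded and control libraries of day 54, and 0.953 and 0.965 in sterile and control libraries of day 35. Fits of only the groups of day 54 or of day 35 leave the less alike groups out. A pseudocount of 5 gave 1 gene at day 45, 393 at day 54 and 95 for sterile leaves at day 35. The fit of only the compared groups gave 0, 2096 and 1119, and the fit without the initial libraries gave 696 at day 54 and 804 for sterile leaves. DESeq2 gave 130, 1375 and 826 on the recovered counts and 107, 1294 and 613 on halved counts; it leaves some genes without an adjusted p. EdgeR gave 0 genes at day 45 on the recovered counts (3075 at an unadjusted p under 0.05) and 0 on halved counts (3217), and 101 for sterile leaves on halved counts. With the title numbers, the counts were 3800 at day 64, 8265 at day 76, 5070 for the difference between days 76 and 45, 1385 for that between days 76 and 64, and 47 for opposite calls. Leaving out a library gave 0 to 19 genes at day 45, 23 to 155 at day 54 and 5 to 33 for sterile leaves at day 35. The overlap of day 54 with sterile leaves of day 63 (186 genes the same way) and the T295H time genes at day 54 (220) depend on the calls of day 54: a pseudocount of 5 gave 290 and 341, the compared groups 1545 and 1769, DESeq2 1012 and 1155, DESeq2 on halved counts 952 and 1092, the fit without the initial libraries 520 for the former, and leaving out a library 18 to 180 and 23 to 218.

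With the replicate number as a block, 0 genes were called at day 45 and 708 for sterile leaves at day 35, and no other count moved by over 1.5 times. Whether the numbers pair samples stays open. In no comparison did deviations of all 3 same-numbered pairs correlate over 0.1. Own numbers matched best for 0 to 5 of the 6 libraries (5 for sterile leaves at day 63), a weak hint only. Of the log2 changes of named genes under alternatives, 528 kept their direction and call and 34, of 8 genes, kept their direction and lost the call. The gene lists by product name, with their estimated correlation and block, were not run, because no ID matched a name. Depth limits the lowest groups: a fold against no count rests on the floor of 6 counts per library.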

Other observations

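All values in this part were chosen after the data were seen. In depodded leaves, a few genes held much of the counts. Of the 10 genes with the highest mean over the depodded libraries of days 54, 64 and 76 by label, 4 stood at least 100 times above their control mean, at 139 to 827 times. These 4 were chosen by their values on those days, so a high share there in depodded leaves and a low share in controls follows from the choice. Values at day 45, in initial leaves and in T295H played no part in it. Together these 4 held between 4.41% and 10.5% of counts in the 3 depodded libraries of day 54, between 7.27% and 13.9% at the label of day 64 and between 5.73% and 7.96% at that of day 76, against at most 0.149%, 0.053% and 0.00862% in controls. At day 45 they held 4.18% ± 5.3 in depodded leaves (1.05% to 10.2%), but 1.15% without replicate 3, against 0.404% ± 0.051 in controls and 0.489% ± 0.13 in the initial leaves of Williams 82 (n = 3 each). In T295H they held between 0.558% and 0.814% in initial leaves and, at day 35, between 1.31% and 2.35% in sterile and 0.356% to 0.997% in control leaves. At day 63 they held between 0.0918% and 0.524% in sterile leaves, less than in initial leaves, and at most 0.00122% in controls.

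As a baseline from the overlap above, 4125 of the 6768 genes higher at the label of day 76 and tested in both lines were also higher in sterile leaves at day 63. Of 6242 lower genes, 3404 were also lower there. The genes called at day 54 are a closer baseline, since the sets below also required a call at day 54. Of 147 genes higher at day 54 and tested in both lines, 113 were higher in sterile leaves at day 63. Of 94 lower ones, 73 were lower there. Genes called higher in depodded leaves at day 54 and at both later labels numbered 108, and 102 of them were tested in T295H, where 84 were higher, 1 was lower and 17 were not called in sterile leaves at day 63. Those called lower on all 3 numbered 38, and the 37 of them tested in T295H were lower in sterile leaves at day 63. Without depodded replicate 1, 2 or 3 of day 54 the former numbered 19, 18 and 86 and the latter 0, 3 and 24, and without control replicate 1, 2 or 3 they numbered 21, 62 and 55, and 3, 8 and 24. Both sets follow the time labels in doubt and were not formed with the title numbers. Of the genes called at day 54 and tested in both lines, 113 were higher in both (39 for independent lists), 73 lower in both (23) and 4 opposite. Genes the same way in both, 186 with all libraries, numbered 18, 21 and 113 without depodded replicate 1, 2 or 3 and 22, 65 and 94 without control replicate 1, 2 or 3. They numbered 290 with a pseudocount of 5, 1545 in the fit of only the compared groups, 520 in the fit without the initial libraries, and 1012 with DESeq2 (952 on halved counts).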
